A study of Dolichospermum flos-aquae with 6 samples.

How the data were processed

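Total RNA of Dolichospermum flos-aquae was sequenced after rRNA depletion, in 3 control and 3 sonicated samples. Per the labels' protocols, each of 3 separate cultures was divided into a control part and a sonicated part. The p-values of the main fit measure the spread between cultures within each group and do not use this pairing. The alternative with culture as a block uses it. Cells were grown at 26 °C under 1% CO2, and the labels name a library kit without strand marking. Whether the counting used strand is not given in the sources used here. Reads from a gene and from the opposite strand were therefore taken as not separable, and values of overlapping genes are uncertain.

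The authors deposited 1 table of raw read counts per gene for each library, with contig, start, end, strand and length of each gene per the file headers. The deposited counts are whole numbers that were not normalised. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.36, Bowtie2 2.2.6, featureCounts of Subread 1.5.2 and DESeq2, without roles or settings; the name of the genome build is not given in the sources used here. Coordinates are those of the count tables, counted from 1. The files pair locus tags with no product, and genes of the same symbol share 1 count, which holds for 49 names that span more than 1 interval. The authors also deposited a table of their comparison, which gives a log2 fold change, a p-value and an adjusted p-value per gene. Its 6 columns of normalised signal are, as tested on the values, the deposited counts divided by 1 size factor per library. DESeq2 run with group alone on the 4602 genes of that table gave log2 values within 3.17e-05 of the deposited ones and 205 calls. The 50 genes not listed there have at most 60 reads over the 6 libraries and the listed genes at least 64.

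Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes with low counts were left out with filterByExpr (minimum count 10, minimum total 15), which kept 4607 of 4652 genes, and libraries were scaled by TMM. The quasi-likelihood fit was robust with group as its only term, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Standard errors come from the log2 fold change and the F statistic of the same test. The biological coefficient of variation was 13.6%. Normalised read counts are CPM on the TMM scale, and log2 differences within a culture use a prior count of 2. Gene lists were tested with camera in limma 3.58.1 (preset correlation of 0.01) on log2 CPM, with camera with an estimated correlation, and with fry. Of 43 lists written as patterns of gene symbols, 24 had at least 3 tested members and were tested, 19 had fewer, and 11 of these had none; since only symbols could be matched, the lists cover 282 genes. Groups, the main tests, the lists, the alternatives other than those named as added and the rule for named genes were set before the data were examined. Some symbol patterns also matched genes of another function: metX, cysT and hisG in the synthetase list, cysS in the sulfur list, ftsY in the cell wall list and hemW in the pigment list. The lists were kept as written, and testing them without these members was an alternative added after seeing the data.

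The rule for named genes took every gas vesicle gene; the 10 largest rises and 10 largest falls among genes that passed the test, moved one way in all 3 cultures and have a known product, read here as having a gene symbol (6 rises and 1 fall passed); the 2 largest rises and 2 largest falls whatever the product; and up to 3 members with the smallest p of each list described.

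The culture letters pair the samples, since the protocol in the labels divides each culture. Deviations from the group means correlated across genes at 0.13 between control A and sonicated A, 0.18 for B and 0.20 for C. Replicates of a group were compared by a chi-square test of their counts over genes. The statistic was 27.7 to 134 times its degrees of freedom for pairs of control libraries and 32.5 to 597 for sonicated ones. No library was thus a repeat of another in its group, and pairs across the groups were not compared this way.

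The main fit was tested on simulated data, with counts drawn from the means, dispersions and library sizes of these samples and 200 genes changed by known folds. In this simulation of sonicated against control, 4596 genes were run. The test recovered 59.7% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 98.4% of those changed 4-fold. Of its 173 calls, 4.62% were false. A further 20 genes were raised by a smaller fold and did not count as false when called. Each count was drawn independently, without culture effects, a library that stands apart or correlation between genes. The rates therefore hold for such data and may not hold for these samples.

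Alternatives were culture as a block, a correction for gene length with and without the block, DESeq2 size factors, library totals alone, no filter, a filter at a mean count of 50, DESeq2 1.42.0, limma-voom, structural RNA genes left out, and each library or culture left out in turn. Structural RNA genes were taken as ssrA, ssrS, rnpB, ffs and rrf, unnamed genes of rRNA size within 6000 bp of a copy of rrf, and genes under 100 bp whose length is not a multiple of 3, which made 49 genes. In the DESeq2 and limma-voom alternatives the lists were tested with cameraPR on the statistics of those tools. Figures were drawn with matplotlib 3.10.9. The other hosts named in the title of the series were not analysed here.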

Results

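RNA was sequenced from Dolichospermum flos-aquae CCAP 1403/13F, a filamentous cyanobacterium that floats by means of gas vesicles, which are gas-filled protein shells inside the cell that collapse under pressure. The series asks how transcription responds when these shells are collapsed. Per the labels, 3 separate 50 ml cultures (A, B and C) at an OD600 of 2.0 were each divided into 25 ml parts. One part of each culture stayed at room temperature as the control, and the other was sonicated in a water bath in 3 bouts of 10 seconds to collapse the vesicles. The 6 libraries, depleted of rRNA, form a control group and a sonicated group with n = 3 each. Reads assigned to genes totalled 25212015 to 26500751 per control library and 21548364 to 30363862 per sonicated library. Of the 4652 gene names in the count tables, 636 are gene symbols and 4016 are locus tags with no product. The sonicated library of culture A stood apart from the other 5. In it, 5 unnamed genes of 2826 to 2832 bp that lie beside the 5 copies of the 5S rRNA gene rrf took 37.8% of the reads (Wilson 95% interval 37.7% to 37.8%), against 19.0% to 22.6% in the others. Such intervals cover counting error only.

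Sonicated cells held more transcript of 4 genes of protein-folding chaperones and heat shock proteins. The transcript of clpB, which encodes a disaggregase that pulls proteins out of aggregates, rose from 110 ± 12.2 to 903 ± 118 CPM, which are normalised read counts (mean ± SD, n = 3 per group), which is 8.20-fold. That of htpG, the bacterial Hsp90, rose 4.98-fold, from 157 ± 16.9 to 782 ± 233 CPM. The Hsp70 gene dnaK rose 4.15-fold, from 422 ± 46.8 to 1750 ± 179 CPM, and dnaJ, its co-chaperone, rose 2.06-fold, from 79.2 ± 10.8 to 163 ± 3.46 CPM. Each of the 4 was higher after sonication in 3 of 3 cultures. The log2 fold changes by edgeR's quasi-likelihood test were 3.03 ± 0.15 (SE; Benjamini-Hochberg adjusted p = 2.89e-06) for clpB, 2.32 ± 0.22 (adjusted p = 3.45e-04) for htpG, 2.05 ± 0.14 (adjusted p = 2.84e-05) for dnaK and 1.04 ± 0.11 (adjusted p = 8.17e-04) for dnaJ.

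The list of chaperone and heat shock genes had 8 tested members, of which 4 rose and 4 did not pass the test over all genes. Adjusted over the list alone, 7 of the 8 passed. The members that did not pass over all genes are named here after their values were seen. The log2 fold change was 0.72 ± 0.19 (edgeR adjusted p = 0.0929) for groES and 0.47 ± 0.13 (adjusted p = 0.0952) for groL, which encode the GroES-GroEL folding chamber. It was 0.33 ± 0.12 (adjusted p = 0.205) for grpE, the nucleotide exchange factor of DnaK, and 0.11 ± 0.12 (adjusted p = 0.649) for hrcA, a repressor of heat shock genes. With scaling by library totals alone hrcA had -0.060, where the median of all genes was -0.14. Culture A, whose sonicated library stood apart, had the largest difference for groES, at 1.17 on the log2 scale against 0.45 in B and 0.46 in C, and the smallest for clpB, at 2.70 against 3.09 and 3.30. As a set the list was higher in sonicated cells, with a median log2 fold change of 0.88 (camera with a preset correlation, adjusted p = 1.02e-09). With an estimated correlation it did not pass (adjusted p = 0.0816 with an estimated correlation), while fry gave an adjusted p of 7.30e-04. In some alternatives edgeR called groES, namely with the block and length correction (adjusted p = 0.0364), without sonicated A (0.0239), without sonicated C (0.00693) and without culture C (0.0329), and groL, namely without sonicated A (0.0397) and without sonicated C (0.0178), while grpE was called without sonicated C (0.0423). The counts of clpB and dnaK each sum 2 loci, those of groL 2 and those of grpE 3, so the share of each copy is uncertain. Without culture B, dnaJ no longer passed (log2 fold change 1.13, edgeR adjusted p = 0.0520).

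**Figure D1:**
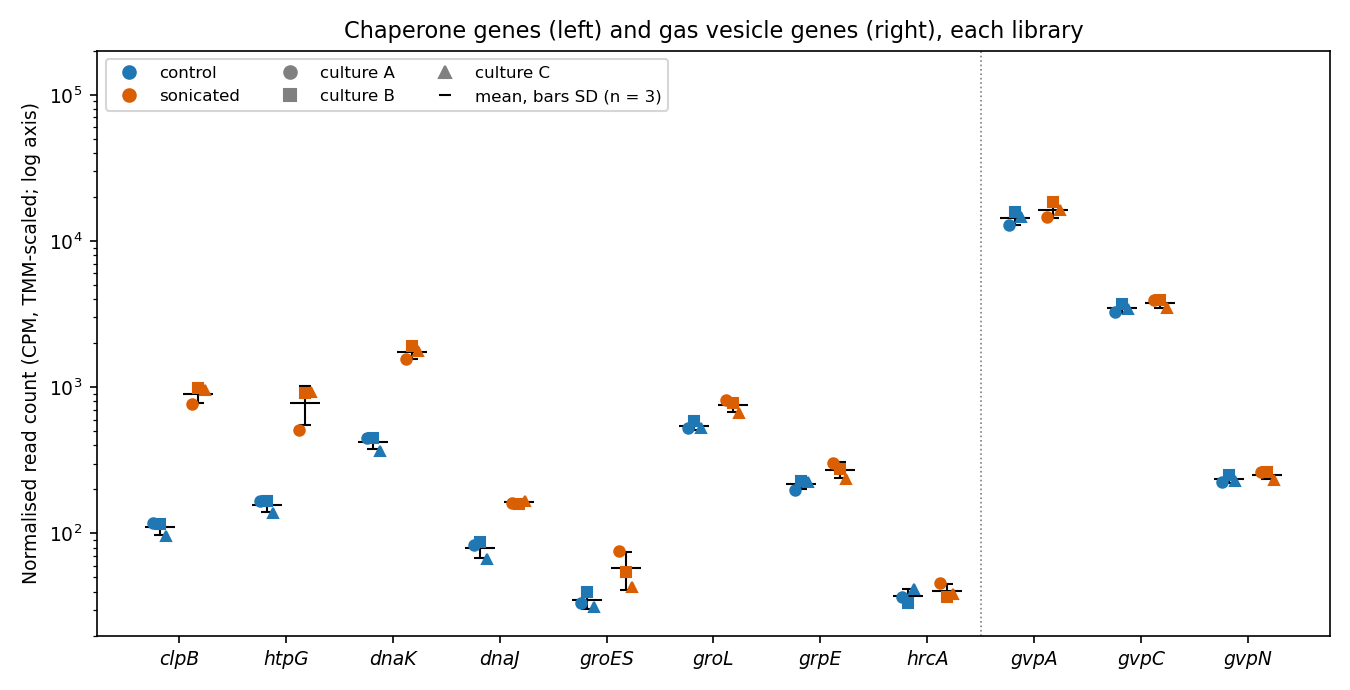
Normalised read counts (CPM on a log axis, scaled by TMM) of the 8 chaperone genes and the 3 gas vesicle genes in each library. Blue points are control and orange points sonicated libraries, symbol shapes mark cultures A, B and C, and black bars give mean and SD (n = 3). Mean clpB was 110 CPM in control and 903 CPM in sonicated libraries, while gvpA had means of 14374 and 16357 CPM.

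None of the 3 gas vesicle genes passed the test, and gvpA and gvpC were abundant in both groups. The ribs of the vesicle wall are built of GvpA, and its gene gvpA ranked next among the gene symbols by mean level in the control libraries after the tmRNA gene ssrA and the photosystem II gene psbA. It had 14374 ± 1469 CPM in control and 16357 ± 1954 CPM in sonicated cells (n = 3 each), a log2 fold change of 0.19 ± 0.18 (edgeR adjusted p = 0.610). For gvpC, whose protein strengthens the wall from outside, the log2 fold change was 0.13 ± 0.14 (adjusted p = 0.652). For gvpN, an ATPase of vesicle assembly with a mean of 234 CPM in control and 252 CPM in sonicated cells, it was 0.11 ± 0.11 (adjusted p = 0.609). By edgeR 0 of the 3 passed, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Adjusted over the list alone, 0 of the 3 passed. The list had a median log2 fold change of 0.13 (camera adjusted p = 0.319), and of -0.030 with scaling by library totals alone, where gvpC and gvpN also lay below 0. On that scale the median of all genes was -0.14.

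On the first contig in the count tables, the gvpA count sums 7 tandem copies between 273241 and 275369 on the minus strand, followed on that strand by gvpC at 272469 to 273050 and gvpN at 271164 to 272171. Reads from near-identical copies cannot be assigned to one of them. The next 4 genes downstream on that strand, all without a name in the files, had log2 fold changes of 0.12 to 0.31. Among 18 neighbours between 261023 and 285445, edgeR called 0, with 5 at an unadjusted p under 0.05 and 2 called by DESeq2.

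**Figure D2:**
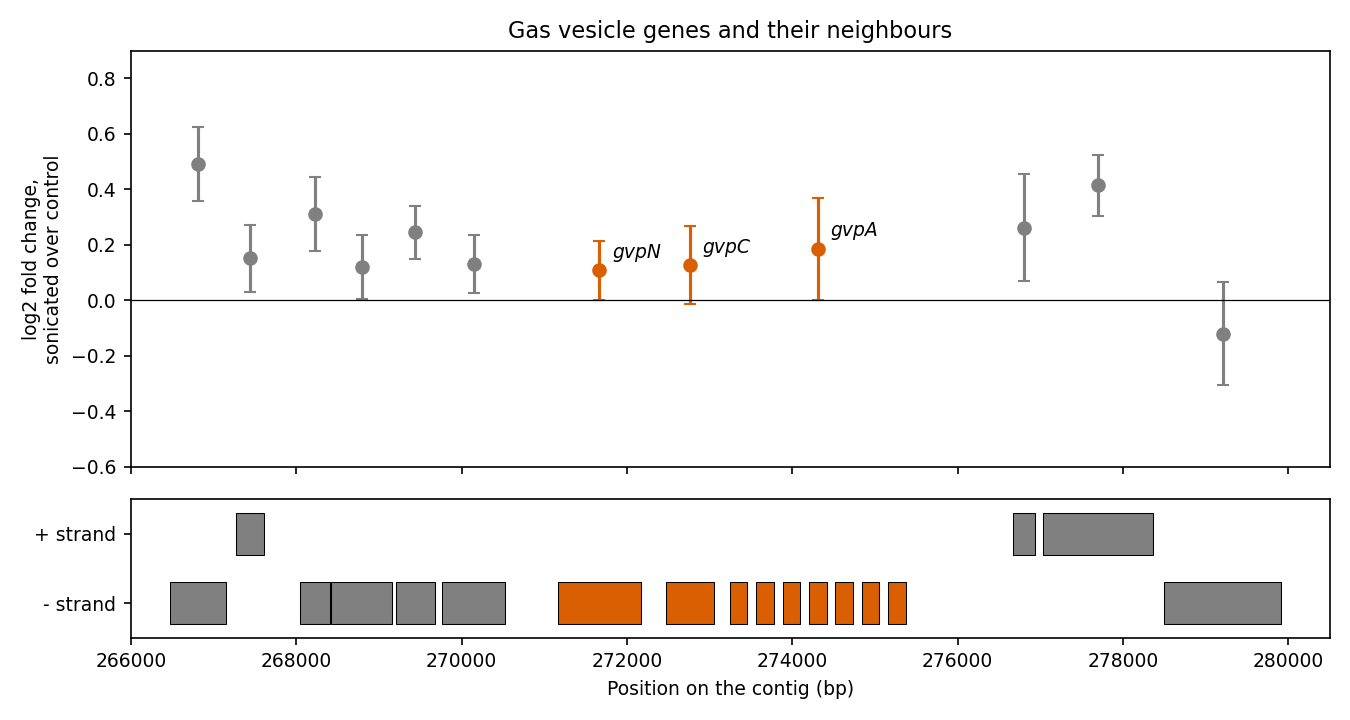
Log2 fold change of sonicated over control (points, with bars of 1 SE) for gvpN, gvpC and gvpA (orange) and neighbouring genes (grey), above a map of their positions in bp and strands. The 7 boxes for gvpA are its copies, which share 1 count. The estimates for the gvp genes are 0.11, 0.13 and 0.19.

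Across the genome 45 genes rose and 25 fell after sonication among 4607 tested, and all 70 moved one way in all 3 cultures. Of the 4607, 822 had an unadjusted p under 0.05 by edgeR, which is the background for the counts of such genes per list. At least 2-fold changes made up 24 of the 70, with 21 higher and 3 lower. Gene symbols are attached to 7 of them, and the other 63 carry only a locus tag. Besides the chaperones, hemW and purB rose. HemW is known in other bacteria as a haem chaperone, and its gene rose 5.67-fold (log2 fold change 2.50 ± 0.29, edgeR adjusted p = 0.00209; 1.57, 2.48 and 3.36 in cultures A, B and C). The gene of adenylosuccinate lyase in purine synthesis, purB, rose 1.92-fold (0.94 ± 0.09, adjusted p = 3.85e-04). Without culture B neither passed (adjusted p = 0.0563 for hemW and 0.0584 for purB), and with scaling by library totals alone purB had an adjusted p of 0.203.

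The largest rises of all belonged to 2 short genes for which the files give no product. HGD76_RS24170, at 5080993 to 5081307 on the minus strand, rose 9.11-fold (3.19 ± 0.16, edgeR adjusted p = 2.89e-06). HGD76_RS07995, at 1636678 to 1637022 on the minus strand, rose 8.38-fold (3.07 ± 0.19, adjusted p = 1.52e-05). The largest falls among called genes were those of HGD76_RS15205 at 3145863 to 3146201, with a log2 fold change of -1.37 ± 0.21 (adjusted p = 0.0162), and HGD76_RS09550 at 1964723 to 1964992, with -1.16 ± 0.23 (adjusted p = 0.0389). Without control A, control B or sonicated B neither fall passed (adjusted p = 0.0675, 0.0563 and 0.0617 for the first and 0.225, 0.222 and 0.219 for the second). HGD76_RS15205 also failed without sonicated A (0.168), and HGD76_RS09550 with library totals alone (0.121) and with limma-voom (0.0561), while both rises passed in all 19 alternatives. Without culture A the first fall had an adjusted p of 0.138, and without culture B the falls had 0.242 and 0.868.

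**Figure D3:**
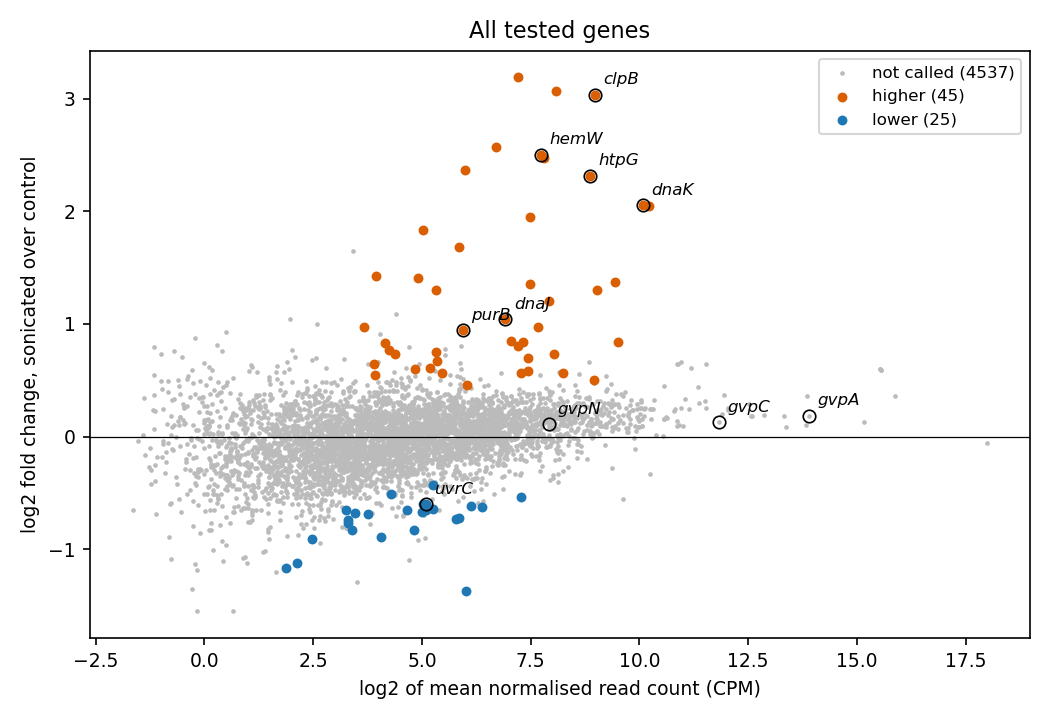
Log2 fold change of sonicated over control against the log2 of the mean normalised read count (CPM) for each tested gene. Orange points are the 45 genes called higher, blue the 25 called lower and grey the 4537 not called by edgeR at an adjusted p under 0.05; circles mark genes named in the text. The gvp genes lie near 0, with gvpA and gvpC at the abundant end, and the called rises reach 3.19.

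The counts of changed genes depended on the tool, the scaling and the libraries. DESeq2 called 100 higher and 105 lower, and scaling by library totals alone 20 and 4, with the median of all genes then at -0.14. Leaving out 1 library gave 22 called genes in all without control A and 22 without control B, 44 without control C, 298 without sonicated A, 27 without sonicated B and 379 without sonicated C. Without both parts of culture A, B or C the counts were 135, 12 and 114.

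Among 21 genes of DNA repair, 1 passed, and it fell, while 6 had an unadjusted p under 0.05, DESeq2 called 2, and 4 were called without sonicated A. That gene, uvrC, encodes the nuclease subunit of nucleotide excision repair and fell from 41.2 ± 4.11 to 27.2 ± 3.05 CPM (log2 fold change -0.60 ± 0.12, edgeR adjusted p = 0.0338; lower in 3 of 3 cultures). With culture as a block its adjusted p was 0.0565 and no member of the list was called, and without control A, control B, control C or sonicated B it was 0.186, 0.222, 0.0588 and 0.219, with 0.868 without culture B and 0.511 with library totals alone. Its partners in the pathway did not pass, with 0.33 ± 0.09 (adjusted p = 0.0929) for uvrA and -0.45 ± 0.13 (adjusted p = 0.110) for uvrB. However, uvrA was called higher by DESeq2 (adjusted p = 0.0419) and without sonicated A (0.0381), and uvrB was called lower without sonicated C (0.0144). Adjusted over the list alone, 2 members were higher and 2 lower. The list had a median of -0.10 and did not pass (camera adjusted p = 0.319). With library totals alone its median was -0.25, where the median of all genes was -0.14.

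Ribosomal protein genes and photosystem II genes had small positive medians, with no single member called. The 14 lists outside those described also had medians above 0 (0.09 to 0.19), while the median of all tested genes was 0.0045. Among 51 ribosomal protein genes the median log2 fold change was 0.15, or -0.0082 with scaling by library totals alone, and 44 lay above 0 (camera with a preset correlation, adjusted p = 0.00372; adjusted p = 0.704 with an estimated correlation; fry adjusted p = 0.531). With library totals alone the median of all genes was -0.14. On that scale camera with the preset correlation still called this list (adjusted p = 0.00362) and the photosystem II list (0.0303). Among the ribosomal protein genes the smallest unadjusted p values were those of rpmB (0.45 ± 0.12, edgeR adjusted p = 0.0952), rplL (0.51 ± 0.16, adjusted p = 0.129) and rplJ (0.38 ± 0.12, adjusted p = 0.159). The first of them, rpmB, lies at 2868815 to 2869051 on the minus strand. That is just downstream of htpG (2869213 to 2871180, same strand), which rose 4.98-fold. Whether rpmB moved with htpG rather than with its list was not tested. For the 15 photosystem II genes, whose complex splits water, the median was 0.20, or 0.035 with scaling by library totals alone, and all 15 lay above 0 (camera adjusted p = 0.00712; adjusted p = 0.704 with an estimated correlation; fry adjusted p = 0.435), led by psbF (0.27 ± 0.11, edgeR adjusted p = 0.240), psbQ (0.46 ± 0.22, adjusted p = 0.303) and psbU (0.22 ± 0.11, adjusted p = 0.332). edgeR called 0 of the 51 and 0 of the 15, with 4 and 1 at an unadjusted p under 0.05 and 1 and 0 called by DESeq2, and adjusted over the list alone 0 in either list. Without sonicated C, edgeR called rpmB (adjusted p = 0.0446), rplL (0.0219) and rplJ (0.0319), and it called rpmB also without sonicated A (0.0458) and with the block and length correction (0.0321). The ribosomal protein median was 0.32 in culture A, 0.12 in B and -0.02 in C, and the photosystem II median was 0.37, 0.17 and 0.00. Without the sonicated library of culture A, neither list passed (camera adjusted p = 0.428 for both), and the same held without control C (0.151 and 0.0797). Without sonicated B the ribosomal protein list did not pass (0.0562).

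The lists for light harvesting, nitrogen fixation and pigment synthesis held 1 called gene among them, hemW, and 0 once it was left out. In the phycobilisome list apcA (0.44 ± 0.22, edgeR adjusted p = 0.326), apcB (0.37 ± 0.19, adjusted p = 0.330) and cpcA (0.18 ± 0.16, adjusted p = 0.563) did not pass, and their culture medians were 0.81 in A, 0.19 in B and 0.00 in C. Of 17 genes of nitrogen fixation and heterocysts, the specialised nitrogen-fixing cells of the filament, 15 lay below 0 and 0 passed. Their median was -0.14 (camera adjusted p = 0.204), with -0.28 in culture A, -0.16 in B and -0.05 in C. With library totals alone it was -0.29, where the median of all genes was -0.14. Among them nifK of the nitrogenase had -0.31 ± 0.12 (edgeR adjusted p = 0.231), nifS -0.40 ± 0.16 (adjusted p = 0.237) and hetR, the regulator of heterocyst formation, 0.29 ± 0.12 (adjusted p = 0.243). Among 20 genes assigned to chlorophyll, haem and carotenoid synthesis only hemW passed, and it does not belong to the synthesis steps. The magnesium chelatase gene bchD had -0.33 ± 0.09 (adjusted p = 0.110) and hemJ 0.20 ± 0.09 (adjusted p = 0.273). The phycobilisome list gave a camera adjusted p of 0.215 and the pigment list 0.204. edgeR called 0 of 3 phycobilisome and 0 of 17 nitrogen fixation genes, with 0 and 3 at an unadjusted p under 0.05, and DESeq2 called 0 and 0. Without sonicated C, edgeR called apcA (adjusted p = 0.0465) and nifK (0.0349), and without sonicated A bchD (0.0131). Adjusted over the list alone, 0 phycobilisome and 0 nitrogen fixation genes passed, while 1 pigment gene was higher and 1 lower, and 0 once hemW was left out.

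Aminoacyl-tRNA synthetases and CRISPR-Cas genes had medians near 0, at 0.014 and 0.024. In cultures A, B and C the medians were 0.16, -0.04 and -0.02 for the synthetase list and -0.33, 0.17 and 0.19 for CRISPR-Cas. With library totals alone they were -0.15 and -0.14, near the median of all genes on that scale (-0.14). The 23 genes of the synthetase list include 3 of other functions (metX, cysT and hisG), which its pattern of symbols also matched. Among the 23, cysS (-0.45 ± 0.11, edgeR adjusted p = 0.0741), glyS (-0.36 ± 0.09, adjusted p = 0.0763) and gltX (-0.33 ± 0.12, adjusted p = 0.191) had the smallest p values and did not pass. Among 9 CRISPR-Cas genes the same held for cas2 (-0.69 ± 0.17, adjusted p = 0.0733), cas3 (0.48 ± 0.16, adjusted p = 0.156) and cas4 (0.71 ± 0.33, adjusted p = 0.294). The value of cas4 rests on few reads, a mean of 17.5 per library, with means of 0.52 CPM in control and 0.87 CPM in sonicated cells. edgeR called 0 in each list, with 4 and 2 genes at an unadjusted p under 0.05 and 2 and 1 called by DESeq2. Without sonicated A, edgeR called 2 in each list, cysS (adjusted p = 0.00134), glyS (0.0300), cas2 (0.0280) and cas3 (0.00118). It called cysS (0.00971) and cas3 (0.00220) also without culture A, cysS with the block and length correction (0.0371), cas2 without sonicated C (0.0160) and without culture C (0.0301), and glyS without sonicated C (0.0484). Adjusted over the list alone, 2 synthetase genes were lower, and 1 CRISPR-Cas gene was higher and 1 lower. Both lists gave a camera adjusted p of 0.937. In the 14 other lists with at least 3 tested members, edgeR called 0 of 114 genes, with 9 at an unadjusted p under 0.05 and 2 called by DESeq2. Adjusted over the list alone, 2 calls were made in these lists. Their medians ran from 0.09 to 0.19 and their camera adjusted p values from 0.204 to 0.937. With library totals alone, only photosystem I (0.012) and the sulfur list (0.075) kept medians above 0. The others then ran from -0.16 for the structural RNAs to -0.0012 for the phosphate list, with the median of all genes at -0.14.

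The authors' deposited table of the same comparison named more genes. It lists 4602 genes and, at an adjusted p under 0.05, has 100 higher and 105 lower in sonicated cells. All 70 genes called by edgeR are among those 205, each with the same sign, and 98.5% of the genes in both have the same sign. Both rest on the same counts, and DESeq2 with group alone gave 205 calls and log2 values within 3.17e-05 of the deposited ones. The shared signs and calls are therefore no separate evidence, and the larger number of calls is that of DESeq2. In the authors' deposited table clpB has a log2 fold change of 3.04 (adjusted p = 9.20e-99), hemW 2.51 (adjusted p = 5.45e-21) and gvpA 0.20 (adjusted p = 0.465). The authors' deposited table also calls groES (0.74, adjusted p = 0.0137) and groL (0.48, adjusted p = 0.00953), which edgeR with all 6 libraries and group alone did not, and uvrA (0.34, adjusted p = 0.0425). At an adjusted p under 0.01 in both, 28 genes were called in common.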

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

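The alternatives added after seeing the data are DESeq2 on the genes of the authors' table and 4 lists without members of another function. The filter left out 45 genes whose depth was too low for a test. The 4 called chaperone genes passed in all 19 alternatives, except dnaJ without culture B (adjusted p = 0.0520). Culture as a replicate block gave 45 genes higher and 28 lower, with 57 of the 70 calls shared. It kept 41 of the 45 higher calls but only 16 of the 25 lower ones. The block changed the call of uvrC, and of no other named gene and no list.

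Counts that moved by over 1.5 times were, for genes higher, 71 with the replicate block and gene length correction, 20 with library totals only and 100 with DESeq2; for genes lower 64, 4 and 105; and for genes shared with the authors' calls 127, 24 and 205. Leaving out 1 library or culture gave 12 to 163 genes higher, 0 to 216 lower, 12 to 49 changed at least 2-fold, 12 to 181 shared with the authors, 1 to 8 lists called and 3 to 7 of the 7 named symbols called. The 0 lower genes arose by edgeR without control A, control B, sonicated B or culture B, where 490, 494, 527 and 234 genes had an unadjusted p under 0.05. Without sonicated A 133 were higher and 165 lower, and without sonicated C 163 and 216; the cause was not tested. At an adjusted p under 0.01 the shared calls were 28, and DESeq2 on the listed genes shared 205 with group alone and 115 with the block.

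Library totals only moved the median of all genes to -0.14 and the share of higher genes among calls from 64.3% to 83.3%. On that scale the medians of the gas vesicle list and the ribosomal protein list were -0.030 and -0.0082, and gvpC (-0.030), gvpN (-0.048) and hrcA (-0.060) lay below 0; relative to the shifted median of all genes both lists stayed above it, by 0.11 and 0.13.

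With an estimated correlation 0 lists were called by camera and fry called 1. The medians (0.88 for the chaperone list, 0.15 for ribosomal proteins and 0.20 for photosystem II) do not depend on the list test, so these alternatives tested only the calls. Leaving out libraries or cultures gave medians of 0.047 to 0.255 for ribosomal proteins and 0.097 to 0.290 for photosystem II. With the 4 lists shortened, 3 lists were called.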

Other observations

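The tests of the chaperone genes, of a label exchange in culture A and of neighbouring genes were chosen only after the result was seen; so were the rRNA test on the TMM factor, the lists without members of another function and the rule by which the rRNA test on the SD was set aside, while that test itself and the other splits of the libraries were set before.

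Genes of energy metabolism beyond those described gave small positive medians and no called list. The median log2 fold change was 0.15 over 6 photosystem I genes, 0.16 over 3 genes of ATP synthase, 0.12 over 6 genes of the cytochrome b6f complex and electron carriers, and 0.14 over 14 genes of glycogen and central carbon metabolism (camera adjusted p = 0.319, 0.319, 0.328 and 0.245). In cultures A, B and C the medians were 0.42, 0.06 and -0.03 for ATP synthase, 0.22, 0.11 and 0.05 for cytochrome b6f, and 0.35, 0.05 and -0.02 for glycogen and central carbon, so these 3 were largest in culture A, whose sonicated library stood apart; for photosystem I they were 0.14, 0.22 and 0.12. With library totals alone the medians of ATP synthase (-0.023), cytochrome b6f (-0.023), glycogen and central carbon (-0.026) and the translation factors (-0.034) lay below 0, where the median of all genes was -0.14. The 12 translation factors had a median of 0.12 (camera adjusted p = 0.245) and the 9 genes of the sulfur list one of 0.19 (0.319), or 0.22 over 8 genes (0.194) without cysS, a tRNA synthetase. Both medians were largest in culture A too, at 0.29, 0.06 and -0.02 in A, B and C for the translation factors and 0.30, 0.22 and 0.13 for the sulfur list as written. Tested for change in either direction rather than one way, 4 lists as written passed in fry: the chaperones (adjusted p = 0.00103), the pigment list (0.00257), DNA repair (0.0205) and the synthetase list (0.0213). The pigment list did not pass without hemW (adjusted p = 0.527), the largest of the other log2 fold changes being 0.33 in size. Without metX, cysT and hisG, the 20 aminoacyl-tRNA synthetase genes passed (adjusted p = 0.0336), with 9 above 0 and 11 below. However, fry does not compare a list with the other genes. By edgeR 4 of the 23 genes of the synthetase list as written had an unadjusted p under 0.05, beside 822 of all 4607 tested genes. The pass therefore does not mark the synthetases as changed more than genes in general. In DNA repair 8 members lay above 0 and 13 below.

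Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 70 called genes, 45 of them higher, 25 lower and 24 changed at least 2-fold, and 1 of the 10 splits, the real one, reached each of these counts; the highest other count was 0 in every case. The real split gave 3 called lists, and 4 of the 10 splits gave at least as many, up to 14 in a split of control A, control C and sonicated C from the rest, which parts 1 culture. Among the 4 splits that part all 3 cultures, the highest other count was 0 genes and 8 lists. These list counts used camera with the preset correlation of 0.01. The estimated correlation was 0.51 within the ribosomal protein list and 0.43 within the photosystem II list. Splits that call several times as many lists as the real one show that whole lists move together among these libraries. For such lists the p-values with the preset correlation are too small.

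The 4 chaperone genes called higher were weighed against differences in library make-up. If the unequal share of structural RNAs had made the rise, another scaling or leaving those genes out should have ended it. The smallest log2 fold change of the 4 over these 3 settings was 0.91, with all 4 called. With library totals alone dnaJ had an edgeR adjusted p of 0.0478. Such settings shift all genes about alike. The median of all genes moved only to -0.14 with library totals, 0.015 with DESeq2 size factors and 0.0063 without structural RNA genes. Rises of 1.04 to 3.03 could hardly end that way, so the test shows only that the choice of scaling did not make them. With the trend on gene length removed the smallest was 1.05, against 1.04 in the main fit, and the median of all genes was 0.022. That correction could hardly end such rises either, so it shows only that removing the trend did not lower the smallest one. For clpB and dnaK the length used was a sum over 2 loci. Whether the genes respond to the loss of gas vesicles or to other effects of sonication cannot be told apart, since 0 sonicated libraries without gas vesicles were analysed, so a response to vesicle collapse may hold only as a hypothesis.

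The sonicated library of culture A stood apart, with a TMM factor of 0.70 against 0.98 to 1.13 in the other 5 and the first principal component (46.8% of the variance) highest in it, at 22.2, or 21.1 without the structural RNA genes. Whether less complete rRNA removal lies behind this stays open: without the structural RNA genes its TMM factor was 0.87, nearer to the others (0.93 to 1.08) but still below them. The SD of its log2 deviations from the group mean was then 0.27, against 0.28 with all genes, and sonicated C came close (0.24 and 0.25, the other 4 at most 0.17), though at -3.99 on that component; an SD over 4607 genes can hardly move when 49 are left out, so the outcome set beforehand to exclude this explanation was wrong and that test decides nothing. An exchange of labels between the parts of culture A was argued against by the chaperone list, whose median was 1.07 higher in sonicated A than in control A, with 8 of 8 members above 0. The list was picked after it had been called with culture A included, so its sign in A was partly known. Without culture A the list was still called (median 0.77, camera with the preset correlation, adjusted p = 1.48e-07). Cultures B and C thus gave the same direction without A. A difference in handling or in the response of culture A also stays open, untested.

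Called genes often lay beside another called gene. Of 68 called genes with a single interval, 27 had an adjacent gene called in the same direction. On the same strand 12 neighbouring pairs were called together, against a mean of 0.33 when calls were shuffled over the tested genes (permutation test, 10000 shuffles, p = 1e-04, the smallest they can give), and shuffling within 10 classes of expression level gave the same p. Transcription of such neighbours from 1 promoter is a candidate explanation. On opposite strands 3 pairs were called together, against a mean of 0.18 (permutation p = 8e-04, and 0.0015 within expression classes). One is hemW with an unnamed gene at 2588067 to 2589143 that points away from it (log2 fold change 1.36, edgeR adjusted p = 0.00239), and another is HGD76_RS24170 with the gene at 5080082 to 5080561 (2.37, adjusted p = 0.0338). As the kit does not mark strand, reads of the opposite strand may add to pairs that point toward each other, as the HGD76_RS24170 pair does. The hemW pair points apart, so reads that run on past the end of either gene would not reach the other. Shared regulation stays open too.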
